A study of Mus musculus with 12 samples.

How the data were processed

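Total RNA from the medial prefrontal cortex of female mice, aged 8 to 12 weeks, was made into libraries with a kit that keeps the strand of the RNA, per the labels' protocols. The 12 libraries fall into 4 groups of 3 by genotype and chronic stress, as their titles state. The authors deposited estimated counts per gene symbol, 1 column per library, not normalised. Per the submitters' processing notes, Trim Galore 0.6.6, STAR 2.7.9a, RSEM 1.3.1 and DESeq2 1.36.0 were used with the genome build mm10; the annotation, filters and strand setting are not given in the sources used here. Between 874 and 1032 genes per library carried decimals, which arise where reads are shared out among similar or overlapping sequences, and genes with decimals in at least 6 libraries are reported as uncertain. Genes that overlap another tested gene are named as such where they matter, since the strand setting of the counting is not given.

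The estimated counts were rounded to whole numbers for testing. Totals per library ran from 15469590 to 31082240. A value of 3 counts, the limit that a count of 0 allows, corresponds to between 0.0920 and 0.192 CPM, read counts scaled to library size; such limits cover counting error only. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15199 of 24411; 4800 had no count in any library and 4412 had too few. Libraries were scaled with TMM factors. CPM values use these factors, and log2 CPM uses a prior count of 2. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

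Before the data were examined, 7 comparisons were fixed: stress within each genotype, genotype within each stress level, the interaction, and the averages of stress and genotype. Each was a contrast in 1 edgeR quasi-likelihood fit of all 12 libraries as 4 group means, which leaves 8 residual degrees of freedom and shares 1 estimate of spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and an adjusted p under 0.05 as the threshold, without a fold threshold. Errors of log2 fold changes are standard errors from that fit. A rank or permutation test of 3 against 3 libraries cannot give a p under 0.1, so none is given. In the same way 39 gene lists were fixed, of which 38 could be tested; the list of mitochondrially encoded genes has no member in the table. Lists were tested with camera at a preset correlation between genes of 0.01, and again with a correlation estimated per list and with fry, each adjusted over 38 lists within a comparison. No list call of camera held with an estimated correlation, in any of the 7 comparisons. Counts adjusted over the list alone adjust the same gene p-values within the list.

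Genes were named by a rule set at the same time, with Cacna1g always named. Per comparison it took the 12 largest rises and 12 largest falls among genes past the threshold with a mean log2 CPM of at least 0 and groups that do not overlap (for the averages, the same sign in both parts). Where fewer than 10 genes passed, it also took the 10 smallest p. Per list described it took the 4 members with the smallest p and any member that passed. Gene models without a proper name are counted but not named. Mbp, Dct, Tyrp1, Fos, Akap2 and Otof, named outside this rule, were picked after their values were seen. So were the CPM values of single libraries given for Omp, Cdhr1, Th, Tbx21, Lsp1, Oprk1, Drd5, Ogn, Drd2 and Adora2a. The same holds for those of Scn4b, Pvalb, Mc4r, Nxph3, Chrna5, Mid1, Tsc22d3, Ciart and Padi6. Positions come from GENCODE mouse release 21 on GRCm38, the build named mm10 in the labels, in which 14623 of the 15199 tested symbols (96.2%) were found by name.

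The test was tried on simulated data with the real means and library sizes and known changes. Counts were drawn for each gene on its own, without tissue differences shared by many genes of a library. The recovery and false calls given here are therefore not error rates for the real data. Of 67 genes changed 2-fold, 76.1% were recovered for stress in WT (15097 genes, 3 false calls), 80.6% for stress in KO (15110 genes, 10 false calls), 79.1% for genotype with stress (15096 genes, 6 false calls) and 55.2% for the interaction (15091 genes, 3 false calls). Of 67 genes changed 1.5-fold, fewer were recovered: 52.2% for stress in WT, 32.8% for stress in KO, 52.2% for genotype with stress and 13.4% for the interaction. Replicates were compared before averaging: chi-square per degree of freedom between libraries of a group lay between 5.07 and 71.7, so none was counted as a duplicate.

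Alternatives fixed in advance were DESeq2's size factors in the same test, no filter on low counts, DESeq2 itself, only the groups compared in the fit, the replicate number as a block, 1 surrogate variable, leaving out each library, the 2 other list tests, and leaving out mitochondrially encoded and ribosomal protein genes, which removed ribosomal protein genes alone. Correlations of effects were also taken over genes with a mean log2 CPM of at least 4. Alternatives chosen after seeing the data were leaving out unstressed WT libraries 1 and 2 (also with an estimated correlation for the lists), leaving out either of these with library 3, leaving out 1 and 2 with stressed KO library 1, marker scores as covariates, and counts thinned to the smallest library.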

Results

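RNA was profiled in the medial prefrontal cortex of female mice of 2 genotypes, wild type (WT) and knockout (KO) of Cacna1g, the gene of the Cav3.1 T-type calcium channel. Mice of each genotype were either left unstressed or exposed to chronic stress, a forced swim or tail suspension test once a day for 5 days. The design gave 4 groups of 3 libraries: unstressed WT, stressed WT, unstressed KO and stressed KO. Estimated counts per library summed to between 27020289 and 31082240 in unstressed WT, 24269178 and 29830758 in stressed WT, 20892789 and 26252377 in unstressed KO, and 15469590 and 28022130 in stressed KO. Of 24411 gene symbols, 15199 had enough counts to be tested. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries. WT mice were purchased from a breeder and KO mice came from a bioresource centre, so genotype and colony go together in every comparison of genotypes.

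The targeted gene, Cacna1g, lies on chromosome 11 at 94408391 to 94474198 on the minus strand (GRCm38). Its level was 132.7, 144.1 and 135.3 CPM (normalised read counts scaled to library size) in the unstressed WT libraries 1 to 3 and 128, 109.8 and 109.4 CPM in the stressed WT libraries. In KO it was 65.1, 54.6 and 61.7 CPM without stress and 58.5, 65.95 and 57.6 CPM with stress. All 6 KO libraries were below all 6 WT libraries. The log2 fold change of KO against WT was -1.18 ± 0.09 (SE) without stress and -0.93 ± 0.09 with stress, with edgeR quasi-likelihood adjusted p of 1.0e-04 and 5.2e-04. Stress did not change Cacna1g past the threshold in WT (log2 -0.25 ± 0.09, edgeR adjusted p = 0.0639) or in KO (log2 0.005 ± 0.09, adjusted p = 0.995). Counts per gene do not tell which of the exons the remaining reads come from.

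**Figure D1:**
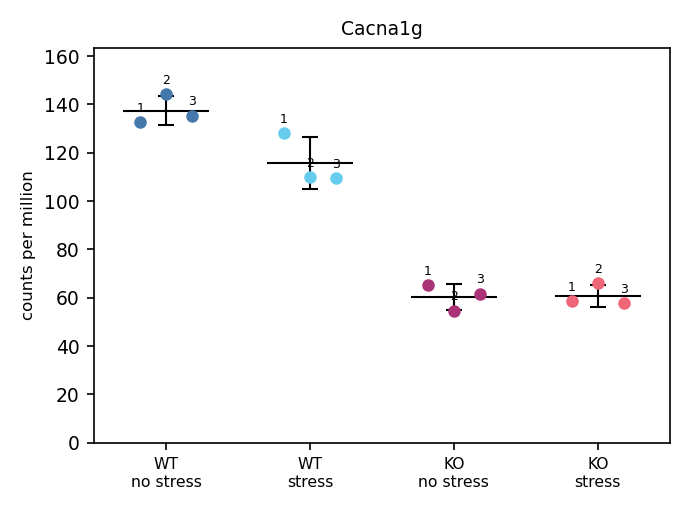
Cacna1g level in CPM (vertical axis) in the 4 groups (horizontal axis). Points are the 12 libraries with their replicate numbers, horizontal lines are group means and error bars are the SD of 3 libraries. The KO libraries lie between 54.6 and 65.95 CPM and the WT libraries between 109.4 and 144.1 CPM.

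Markers of neighbouring tissues differed between libraries of the same group. The score of 14 olfactory bulb markers (mean log2 CPM of the members, centred over the 12 libraries) was 2.47 and 2.39 in unstressed WT libraries 1 and 2, and between -1.33 and 0.58 in the other 10. Cdhr1, a cadherin of olfactory bulb output neurons, stood at 423 and 427 CPM in those 2 libraries and 48.9 CPM in unstressed WT library 3. Tyrosine hydroxylase, Th, stood at 94.2 and 103 against 13.6 CPM. Meningeal and fibroblast markers scored 1.45 and 1.73 in the same 2 libraries and 0.39 in the third, and Ogn, a matrix proteoglycan, stood at 22.6, 24.6 and 6.16 CPM. Striatal projection neuron markers scored 1.71 in stressed KO library 1 and between -0.39 and 0.06 elsewhere, beside Drd2, a dopamine receptor, at 14.3 CPM and Adora2a, an adenosine receptor, at 24.8 CPM in that library. Oligodendrocyte and myelin genes scored 0.82 in stressed WT library 3 and 0.64 in stressed KO library 1, and between -0.39 and 0.29 in the others. Mbp, myelin basic protein, reached 1247 and 1032 CPM in those 2 libraries. Along the first principal component, which held 45.6% of the variance, unstressed WT libraries 1 and 2 stood at -61.9 and -61.1, and the next lowest library at -7.55.

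**Figure D2:**
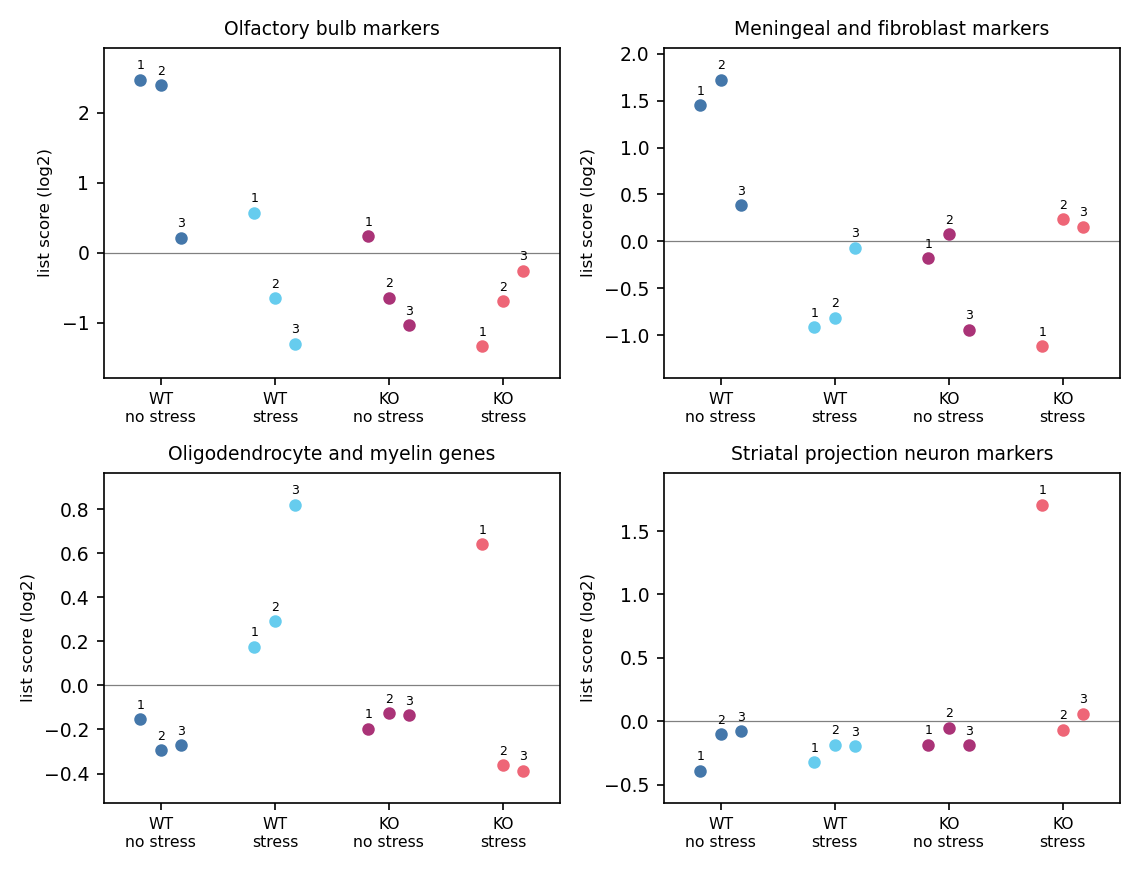
Scores of 4 marker lists (vertical axes, mean log2 CPM of the members centred over all libraries) in the 4 groups (horizontal axes). Points are the 12 libraries with their replicate numbers. Unstressed WT libraries 1 and 2 stand at 2.47 and 2.39 for olfactory bulb markers, and stressed KO library 1 stands at 1.71 for striatal markers.

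The first question was which genes changed with chronic stress in WT mice. By camera at its preset correlation, lists of cholesterol synthesis, oxidative phosphorylation, myelin and immediate early genes were shifted up against other genes in stressed WT, and lists of meningeal and olfactory bulb markers down. With an estimated correlation 0 of 38 lists passed, and not all members of these lists passed singly. Of 24 cholesterol synthesis genes, 15 rose, 0 fell and 9 did not pass; adjusted over the list alone, 19 rose. Msmo1 (log2 0.72 ± 0.11, SE), Hmgcs1 (0.65 ± 0.11), Cyp51 (0.51 ± 0.09) and Fdps (0.55 ± 0.10) were the members with the smallest p. The list rose against other genes (camera adjusted p = 7.0e-09; adjusted p = 0.655 with an estimated correlation), with a median log2 fold change of 0.37. Its scores in the unstressed WT libraries were -0.39, -0.37 and -0.19, the first 2 from the libraries with olfactory bulb scores of 2.47 and 2.39. Of 74 nuclear-encoded oxidative phosphorylation subunits, 16 rose and 0 fell (30 rose adjusted over the list alone), with a median of 0.31 (camera adjusted p = 4.5e-12; adjusted p = 0.655 with an estimated correlation). Uqcrc1 (0.28 ± 0.06) and Atp5g1 (0.40 ± 0.09) were among them, and the list's scores in unstressed WT were -0.11, -0.30 and -0.28. Of 25 oligodendrocyte and myelin genes, 13 rose and 0 fell (18 rose adjusted over the list alone), with a median of 0.77. Mog rose by 1.25 ± 0.25 and Mal by 1.03 ± 0.26. The camera adjusted p of this list was 8.9e-06 (adjusted p = 0.655 with an estimated correlation), and its score was 0.82 in stressed WT library 3 against 0.17 and 0.29 in libraries 1 and 2.

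Among 32 immediate early genes, which neurons switch on within minutes of activity, 9 rose and 2 fell with stress in WT, and 21 did not pass; adjusted over the list alone, 14 rose and 2 fell. Klf10 (log2 0.81 ± 0.11, SE), Ier5 (0.59 ± 0.12), Junb (0.92 ± 0.20) and Arc (1.52 ± 0.36), which acts at synapses, had the smallest p, and the list's median was 0.42 (camera adjusted p = 0.0044; adjusted p = 0.655 with an estimated correlation). Sik1 (-0.89) and Jun (-0.30) were the members that fell. Of 25 genes of endoplasmic reticulum stress and the integrated stress response, 8 rose and 0 fell, with 10 higher and 1 lower adjusted over the list alone. Xbp1 (0.40 ± 0.07), Sdf2l1 (0.56 ± 0.11), Asns (0.45 ± 0.11) and Atf4 (0.28 ± 0.07) led this list. Its median was 0.13, with a camera adjusted p of 0.0044 (adjusted p = 0.655 with an estimated correlation). Immediate early genes scored -0.13, -0.04 and 0.04 in the unstressed WT libraries, whose olfactory bulb scores were 2.47, 2.39 and 0.22, and 0.16, 0.36 and 0.32 in the stressed ones. Circadian clock genes as a list did not pass (camera adjusted p = 0.209), but 5 of 22 rose and 2 fell, also adjusted over the list alone. Dbp (0.61 ± 0.11) and Ciart (0.77 ± 0.15) rose, and Arntl (-0.33) and Cry1 (-0.36) fell. Glucocorticoid-responsive genes did not pass as a list in WT (camera adjusted p = 0.0811), with 5 of 27 higher and 1 lower, also over the list alone.

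Meningeal and fibroblast markers fell in stressed WT, 19 of 21 of them in the test over all genes and over the list alone, with a median log2 fold change of -1.82 (camera adjusted p = 2.0e-08; adjusted p = 0.655 with an estimated correlation). Ogn fell by 3.63 ± 0.62 (SE) and Col3a1, a collagen, by 2.28 ± 0.48. The list's scores were 1.45, 1.73 and 0.39 in unstressed WT and -0.91, -0.82 and -0.07 in stressed WT. Olfactory bulb markers fell for 11 of 14 members (12 adjusted over the list alone), with a median of -2.29 (camera adjusted p = 8.9e-06; adjusted p = 0.655 with an estimated correlation). Members that fell included Sall3 (-2.01 ± 0.39), Th (-3.13 ± 0.70) and Cdhr1 (-3.55 ± 0.89). Outside the lists described so far, the largest rises included Pappa2, a protease of insulin-like growth factor binding proteins (log2 2.34 ± 0.45), and Scn4b, a sodium channel subunit (1.53 ± 0.32, from 28.2 to 81.5 CPM). Others were Pvalb, the calcium-binding protein of fast-spiking interneurons (1.34 ± 0.22, from 10.6 to 26.9 CPM), and Mc4r, a melanocortin receptor (1.35 ± 0.35). Pvalb is 1 of 30 cortical interneuron markers, of which 4 rose and 13 fell (median -0.16, camera adjusted p = 0.119; adjusted p = 0.655 with an estimated correlation), from a mean score of 0.29 to -0.13. Krt80, Sebox, Adamts13, Wnt2, Lypd6b and Tcte1 also rose, Krt80 most, by 2.33, and Aldh1a7, whose estimated counts are split with similar sequences in 11 libraries, rose by 1.47 as an uncertain value. The largest falls were Omp, olfactory marker protein (-6.13 ± 1.35), Shisa3 (-3.95), Eomes, a transcription factor of olfactory bulb projection neurons (-3.85), and Ush1g (-3.76). They also included Klhl30 (-3.75), Aqp1, a water channel (-3.68), Alx4 (-3.59), Trh (-3.37), Rab37 and Wnt6 (-3.27 each). Xlr3b (-3.54) is also uncertain, because its counts are split in 12 libraries. Omp stood at 18.6 and 89.7 CPM in unstressed WT libraries 1 and 2 and at 5.93 CPM in library 3. The largest rises named above, all but Pappa2 and Aldh1a7, were lowest in unstressed WT libraries 1 and 2. In unstressed WT libraries 1 to 3, Scn4b stood at 16.6, 27.75 and 40.3 CPM. Pvalb stood at 8.2, 9.4 and 14.3 CPM there, and Mc4r at 0.72, 1.04 and 2.62 CPM.

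In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3322 genes between stressed and unstressed WT, 1476 higher and 1846 lower. The groups of 5560 genes did not overlap, 36.6% of those tested against 10% by chance. The same edgeR test called 0 genes without unstressed WT libraries 1 and 2, a choice made after seeing the data that leaves 1 library in that group, so that the spread comes from the other groups. With library 1 or library 2 as the 1 library left, also chosen after seeing the data, it called 3335 and 3445 genes. With the olfactory bulb score as a covariate, also chosen after seeing the data, it called 0 as well. The count was 967, 0 and 5635 without unstressed WT library 1, 2 or 3, and 2010, 0 and 1660 without stressed WT library 1, 2 or 3. Against unstressed WT library 3 alone, camera still passed the cholesterol (adjusted p = 4.9e-08), oxidative phosphorylation (1.6e-22), myelin (4.9e-08), immediate early (0.0237), stress response (0.0014) and meningeal (3.6e-06) lists, but not the olfactory bulb list (0.0631). With an estimated correlation 0 lists passed in that fit, and the tissue make-up of a single library cannot be separated from stress there. With all libraries, edgeR gave 5808 genes an unadjusted p under 0.05, DESeq2 called 4019 genes, and edgeR with 1 surrogate variable called 0. With only the compared WT groups in the fit, and so only their own spread, edgeR called 1.

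In KO mice stress changed few genes past the threshold. Dbp, a transcription factor that follows the circadian clock, rose from 55.7 to 110.3 CPM (log2 0.99 ± 0.11, SE, n = 3 per group, edgeR adjusted p = 0.0089). Itgb8, an integrin subunit, fell by 0.79 ± 0.09 (adjusted p = 0.0112), from 27.9 to 16.1 CPM. Pakap fell by 1.35 ± 0.13 (adjusted p = 0.0030), but this gene overlaps Akap2 on chromosome 4 (57568179 to 57896982) and its estimated counts have decimals in 12 libraries, so its value is uncertain. The next 7 genes by p, none of which passed, were Per1 (log2 0.58 ± 0.09, adjusted p = 0.139), Arhgap5 (-0.53, 0.139), Per3 (0.64 ± 0.11, 0.179), Ptprz1 (-0.59, 0.179), Mib1 (-0.72, 0.224), Ciart (0.84 ± 0.15, 0.224) and Ptpn4 (-0.78, 0.341). Per1, Per3 and Ciart are clock genes.

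Of 22 circadian clock genes, 1 rose in stressed KO and 21 did not pass; adjusted over the list alone, 7 were higher and 2 lower. The list rose against other genes. Its median was 0.17, with a camera adjusted p of 6.0e-06 (adjusted p = 0.577 with an estimated correlation). Striatal projection neuron markers rose as a list, with 0 of 19 members passing over all genes and 8 higher adjusted over the list alone. Their median was 0.77, with a camera adjusted p of 6.0e-06 (adjusted p = 0.766 with an estimated correlation). Their score was 1.71 in stressed KO library 1 and -0.07 and 0.06 in libraries 2 and 3, and without that library the camera adjusted p was 0.253. Drd2 (2.89 ± 0.88, SE) and Pdyn (0.77 ± 0.22) did not pass singly. Immediate early genes had 0 of 32 members passing and 4 higher and 1 lower adjusted over the list alone. Their median was 0.27, with a camera adjusted p of 0.0022 (adjusted p = 0.766 with an estimated correlation), with Junb at 0.81 ± 0.20 and Nr4a1 at 0.57 ± 0.17. Scores were -0.16, -0.31 and -0.21 without stress and -0.30, 0.01 and 0.25 with it, so stressed library 1 showed no rise, and without stressed library 3 the list did not pass (camera adjusted p = 0.328). Interferon-stimulated genes had a median of 0.14 and 0 of 30 members passing, over all genes or over the list alone (camera adjusted p = 2.0e-04; adjusted p = 0.766 with an estimated correlation). Blood cell genes moved with them, from scores of 0.38, -0.94 and -0.61 to 0.51, 0.80 and 0.68 (camera adjusted p = 0.0114, and 0.146 without unstressed KO library 3; adjusted p = 0.766 with an estimated correlation). Postsynaptic density genes, with Homer1 at -0.42 ± 0.12 and Shank2 at -0.42 ± 0.14, had a median of -0.18 and 0 of 30 members passing either way (camera adjusted p = 1.2e-04; adjusted p = 0.766 with an estimated correlation). Glucocorticoid-responsive genes did not pass as a list (camera adjusted p = 0.0932), with 0 of 27 members passing and 1 higher adjusted over the list alone.

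In total the edgeR test called 3 genes in KO, 1 higher and 2 lower, with 1398 genes at an unadjusted p under 0.05 and 2569 genes (16.9%, against 10% by chance) with groups that did not overlap. Leaving out unstressed KO library 2 or 3 gave 1 gene each, stressed KO library 1 gave 5, and stressed KO library 2 or 3 gave 1 each. DESeq2 called 44 genes. Without unstressed WT libraries 1 and 2 the count was 3, and also without stressed KO library 1 it was 9.

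Averaged over both genotypes, stress raised 3 genes and lowered 3. Dbp rose (log2 0.80 ± 0.08, SE, edgeR adjusted p = 0.0040), from 52.0 to 79.4 CPM in WT and from 55.7 to 110.3 CPM in KO. Ciart, a repressor in the circadian clock, rose by 0.81 ± 0.11 (adjusted p = 0.0259), and Klf10 by 0.58 ± 0.08 (adjusted p = 0.0297). Itgb8 fell by 0.62 ± 0.06 (adjusted p = 0.0049) and Ptprz1, a receptor tyrosine phosphatase, by 0.53 ± 0.07 (adjusted p = 0.0259); the uncertain Pakap fell by 0.69. Narf (0.26), Itgav (-0.44), Tef (0.28) and Junb (0.86 ± 0.14) followed with adjusted p of 0.0576 each and did not pass. On GRCm38, Dbp lies on chromosome 7 at 45705088 to 45710203, where it overlaps Sphk2, and Ciart on chromosome 3 at 95878503 to 95882251. Other positions are chromosome 15, 38291463 to 38300706 for Klf10, chromosome 12, 119158022 to 119238802 for Itgb8, and chromosome 6, 22875502 to 23052916 for Ptprz1.

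Clock genes rose as a list over both genotypes (2 of 22 passing, 9 higher and 1 lower adjusted over the list alone, median log2 0.11, camera adjusted p = 0.0010; adjusted p = 0.514 with an estimated correlation). Immediate early genes rose likewise (1 of 32 passing, 14 higher and 1 lower adjusted over the list alone, median 0.29, camera adjusted p = 8.7e-05; adjusted p = 0.514 with an estimated correlation), with Arc at 1.38 ± 0.26 (SE). Cholesterol synthesis genes had 0 of 24 members passing over all genes and 15 higher adjusted over the list alone. Their median was 0.19, with a camera adjusted p of 2.4e-08 (adjusted p = 0.514 with an estimated correlation). This average came from WT, where the mean score went from -0.32 to 0.06 with -0.39 and -0.37 in unstressed libraries 1 and 2, while in KO it was 0.13 without and with stress. Myelin genes had 12 of 25 higher adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.568 with an estimated correlation), and their scores of 0.82 and 0.64 came from stressed WT library 3 and stressed KO library 1. Glucocorticoid-responsive genes had 0 of 27 passing and 5 higher adjusted over the list alone. Their median was 0.11, with a camera adjusted p of 0.0088 (adjusted p = 0.514 with an estimated correlation), with Per1 at 0.38 ± 0.07 and Tsc22d3 at 0.33 ± 0.08. Tsc22d3 rose in WT, from between 29.6 and 33.45 CPM to between 44.75 and 57.9 CPM. In KO it lay between 30.2 and 39.8 CPM without stress and between 32.45 and 34.1 CPM with it. Without unstressed WT library 3 the list did not pass (camera adjusted p = 0.0995). Of the 6 genes, only Dbp was called without unstressed WT libraries 1 and 2. The count of 6 became 2, 2 and 3003 without unstressed WT library 1, 2 or 3, 2 without stressed WT library 2 or 3, 2 and 11 without unstressed KO library 1 or 3, and 20, 2 and 2 without stressed KO library 1, 2 or 3; DESeq2 called 1198 genes.

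**Figure D3:**
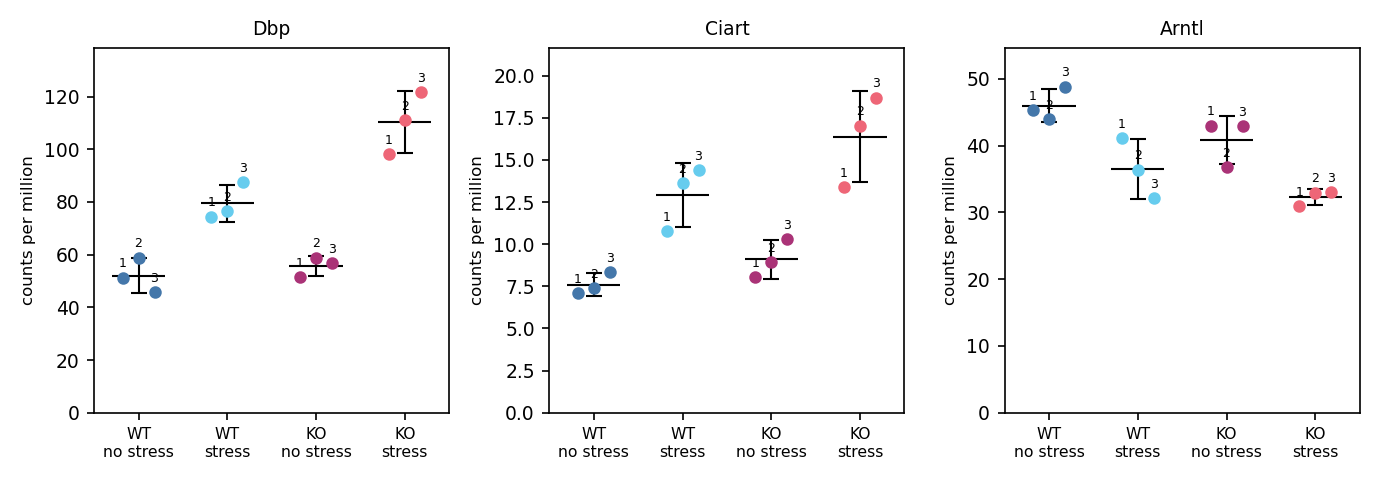
Dbp, Ciart and Arntl in CPM (vertical axes) in the 4 groups (horizontal axes). Points are libraries with their replicate numbers, lines are group means and error bars are the SD of 3 libraries. Dbp lay at 74.4 CPM or more in the stressed libraries and at 58.9 CPM or less in the unstressed ones.

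The next question was how KO differed from WT without stress. Wdfy1, a protein of endosomal signalling, was higher in KO (log2 1.54 ± 0.09, SE, from 24.0 to 69.8 CPM, edgeR adjusted p = 9.9e-06). So were Gabra2, a GABA-A receptor subunit (1.19 ± 0.10, from 45.4 to 103.7 CPM, adjusted p = 1.2e-04), and Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase (0.98 ± 0.08, from 16.4 to 32.4 CPM, adjusted p = 1.2e-04). All 3 belong to a list of 12 genes known to differ between C57BL/6 substrains or used as passenger markers. Of the 12, 3 were higher and 2 lower, over all genes and over the list alone. The lower ones were Erdr1 (-1.57) and Ide (-0.19). As a list these genes did not pass (camera adjusted p = 0.161). Of 22 voltage-gated calcium channel genes, 8 were lower and 0 higher, over all genes and over the list alone. Among them were Cacna1h (-0.63), Cacna1c (-0.61), Cacna1d (-0.57) and Cacna1i (-0.57). The list median was -0.08 and did not pass (camera adjusted p = 0.0945). Its scores were 0.25 and 0.34 in unstressed WT libraries 1 and 2, with strong olfactory bulb markers, 0.13 in library 3, and 0.01, -0.15 and -0.10 in unstressed KO.

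Cholesterol synthesis genes were higher in unstressed KO, 16 of 24 over all genes and 18 adjusted over the list alone, with a median log2 fold change of 0.44 (camera adjusted p = 3.6e-10; adjusted p = 0.791 with an estimated correlation). Fdps (0.80 ± 0.10, SE), Idi1 (0.72 ± 0.10), Hmgcs1 (0.73 ± 0.11) and Msmo1 (0.73 ± 0.11) had the smallest p. Oxidative phosphorylation subunits were higher for 37 of 74 members (51 adjusted over the list alone, median 0.36, camera adjusted p = 4.8e-13; adjusted p = 0.791 with an estimated correlation). Cytosolic ribosomal protein genes were higher for 20 of 77 (33 adjusted over the list alone, median 0.35, camera adjusted p = 7.2e-09; adjusted p = 0.821 with an estimated correlation). Scores within unstressed KO were 0.05, 0.40 and -0.04 for the oxidative phosphorylation list and 0.10, 0.52 and -0.17 for the ribosomal list, with library 2 highest in both. In unstressed WT they were -0.11, -0.30 and -0.28 for the first list and 0.01, -0.22 and -0.25 for the second. Ribosomal scores of the 2 groups thus overlapped, with KO library 3 below WT library 1, and WT library 3 was the lowest. Microglia markers were higher for 5 of 20, also over the list alone. Their median was 0.20, with a camera adjusted p of 0.0090 (adjusted p = 0.821 with an estimated correlation), including Aif1 (1.11 ± 0.19), Gpr34 (0.58 ± 0.14) and P2ry12 (0.36 ± 0.11). Microglia scores were 0.07, 0.33 and -0.09 in unstressed KO, so that library 3 stood near the -0.10, -0.22 and -0.12 of unstressed WT, and without library 2 the list did not pass (camera adjusted p = 0.122). Against these stood olfactory bulb markers, lower for 12 of 14 members and for 14 adjusted over the list alone (median -2.79, camera adjusted p = 7.3e-06; adjusted p = 0.791 with an estimated correlation). Meningeal markers were lower for 16 of 21 and for 19 adjusted over the list alone. Their median was -1.58, with a camera adjusted p of 8.5e-07 (adjusted p = 0.791 with an estimated correlation). Olfactory bulb scores were 2.47, 2.39 and 0.22 in unstressed WT and 0.24, -0.64 and -1.04 in unstressed KO.

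Oligodendrocyte precursor markers were lower in unstressed KO for 5 of 12 members and higher for 1 (6 and 1 adjusted over the list alone), with Gpr17 at -0.61 ± 0.10 (SE) and Vcan at -0.62 ± 0.15. Their median was -0.45, with a camera adjusted p of 0.0433 (adjusted p = 0.791 with an estimated correlation). Glucocorticoid-responsive genes were lower for 6 of 27 and higher for 1, also over the list alone. Their median was -0.24, with a camera adjusted p of 0.0433 (adjusted p = 0.791 with an estimated correlation). Plin4 (-1.64 ± 0.27), Wnk4 (-2.97 ± 0.57), Fkbp5 (-0.41 ± 0.08) and Per1 (-0.41 ± 0.09) led the falls of that list. The precursor list did not pass without unstressed WT library 2 or 3 (camera adjusted p = 0.0579 and 0.0791) or unstressed KO library 1 or 3 (0.0702 and 0.102). The glucocorticoid list did not pass without unstressed WT library 1 or 2 (0.0608 and 0.0599) or unstressed KO library 1 or 3 (0.0702 and 0.140). The largest rises of single genes began with Padi6 (2.47 ± 0.77), Krt80, Pappa2 and Chrna5, a nicotinic receptor subunit (1.98 ± 0.50). Sebox, Wfdc18, Lsp1, Nxph3, Adamts13, Cabp7, Wnt2 and Trpv6 (1.56 ± 0.37) followed. All of them but Pappa2 were lowest in unstressed WT libraries 1 and 2, with their strong olfactory bulb markers. In unstressed WT libraries 1 to 3, Nxph3 stood at 6.33, 11.7 and 36.4 CPM and Chrna5 at 1.07, 1.44 and 3.08 CPM. Padi6 stood at 0.21, 0.03 and 1.06 CPM there, from 6, 1 and 32 counts, and at 1.87, 2.15 and 3.19 CPM in unstressed KO. Its fold thus rests on very low counts in libraries 1 and 2. The largest falls included Omp (-5.68 ± 1.31), Tbx21 (-4.23 ± 1.00), Th (-3.75 ± 0.73), Eomes, Aqp1, Ppm1j, Alx4, Wnk4, Aim1, Ogn and, with split counts in 11 libraries, Clca3a1 (-2.79). The chemokine gene Ccl21b, annotated on the scaffold GL456350.1 and uncertain because its counts are split in 7 libraries, stood at 22.6 CPM in unstressed WT and 0.18 CPM in unstressed KO, with 0, 12 and 0 counts in the 3 KO libraries.

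EdgeR called 3529 genes between unstressed KO and WT, 1697 higher and 1832 lower in KO, and the groups of 5547 genes (36.5%, against 10% by chance) did not overlap. It called 18 without unstressed WT libraries 1 and 2, all 18 among the 3529; these compare KO with 1 WT library, and the other groups supply the spread. With library 1 or library 2 as the 1 library left, it called 3354 and 3406. The 18 included Wdfy1 (1.72), Nnt (1.04), Gabra2 (1.22), Cacna1g (-1.16) and Otof (-1.37), the last outside the naming rule and picked after its value was seen. With only the compared groups in the fit edgeR called 18, and with 1 surrogate variable 17. The count was 1542, 234 and 5729 without unstressed WT library 1, 2 or 3, and 988 and 1922 without unstressed KO library 2 or 3. Against unstressed WT library 3 alone, whose tissue make-up cannot be separated from genotype, camera still passed the cholesterol (adjusted p = 3.9e-09), oxidative phosphorylation (4.6e-22), ribosomal (4.9e-19), microglia (0.0058), meningeal (0.0019) and oligodendrocyte precursor (0.0217) lists. It did not pass the olfactory bulb (0.0740) and glucocorticoid-responsive (0.247) lists, and with an estimated correlation 0 lists passed in that fit.

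After stress, Wdfy1, Gabra2 and Nnt were again higher in KO than in WT, and a small set of other genes differed. Wdfy1 was higher in stressed KO (log2 1.90 ± 0.10, SE, from 18.02 to 67.24 CPM, edgeR adjusted p = 1.2e-06), Gabra2 by 1.26 ± 0.10 (from 36.96 to 88.54 CPM, adjusted p = 7.9e-05) and Nnt by 0.83 ± 0.08 (from 16.8 to 29.9 CPM, adjusted p = 4.5e-04). Their positions on GRCm38 are chromosome 1, 79702262 to 79776143 for Wdfy1, which overlaps Mrpl44, chromosome 5, 70957597 to 71095849 for Gabra2, and chromosome 13, 119335448 to 119408997 for Nnt. Cfap46 (1.41 ± 0.25), Nadsyn1 (1.27 ± 0.20) and Epha8, an ephrin receptor (1.16 ± 0.18, from 4.21 to 9.41 CPM), were also higher, followed by Col6a2 (0.99), Mcm6 (0.73), Mtg1 (0.56) and Tsr2 (0.34). Besides Cacna1g, lower genes were Gpr17, a receptor of oligodendrocyte precursors (-0.77 ± 0.10), Gadd45a (-0.67 ± 0.12), Itgb8 (-0.66 ± 0.09) and the glucocorticoid-induced Tsc22d3 (-0.62 ± 0.11). Values of genes whose estimated counts are split with similar sequences in 7 or more libraries are uncertain. These were Srp54b (1.08), Plac9b (-3.51), Tmem254a (-2.46), Tmem254b (-2.32), Plac9a (-2.13), Fam205a2 (-1.79), Pakap (-1.06) and Ccl21b, which stood at 30.4 CPM in stressed WT and 0.20 CPM in stressed KO (0, 6 and 5 counts).

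**Figure D4:**
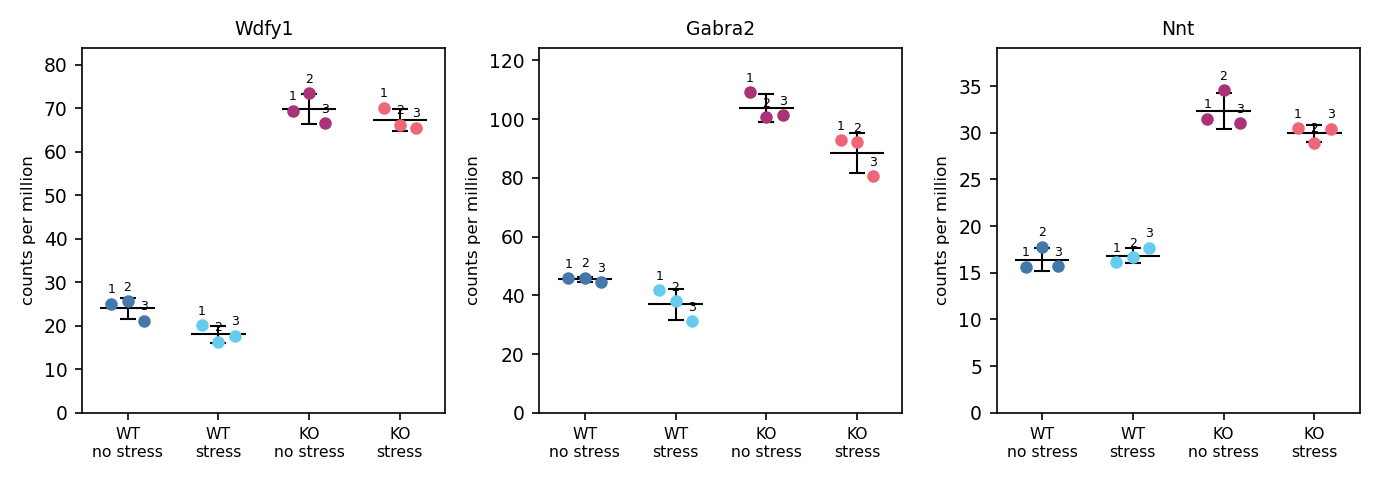
Wdfy1, Gabra2 and Nnt in CPM (vertical axes) in the 4 groups (horizontal axes). Points are libraries with their replicate numbers, lines are group means and error bars are the SD of 3 libraries. Wdfy1 lay between 16.3 and 25.7 CPM in the WT libraries and between 65.5 and 73.4 CPM in the KO libraries.

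Genes of endoplasmic reticulum stress and the integrated stress response were lower in stressed KO, 1 of 25 over all genes and 9 adjusted over the list alone. Their median was -0.17, with a camera adjusted p of 2.5e-07 (adjusted p = 0.393 with an estimated correlation). Atf4, the transcription factor of that response, was the member that passed (-0.49 ± 0.08, SE), and Chac1 (-0.65 ± 0.13) and Herpud1 (-0.28 ± 0.07) did not. Glucocorticoid-responsive genes were lower for 2 of 27, Klf9 (-0.45 ± 0.08) and Tsc22d3, and for 4 adjusted over the list alone. Their median was -0.21, with a camera adjusted p of 1.7e-06 (adjusted p = 0.393 with an estimated correlation). Immediate early genes had 0 of 32 passing, and 1 higher and 5 lower adjusted over the list alone. Their median was -0.25, with a camera adjusted p of 2.6e-04 (adjusted p = 0.507 with an estimated correlation), with Egr1 at -1.09 ± 0.26; without stressed KO library 1 the camera adjusted p was 0.0636. Potassium, sodium and HCN channel genes had 0 of 45 passing and 3 lower adjusted over the list alone. Their median was -0.21, with a camera adjusted p of 1.7e-06 (adjusted p = 0.507 with an estimated correlation), led by Kcnh7 (-1.05 ± 0.25) and Scn1a (-0.57 ± 0.14). Interferon-stimulated genes had a median of 0.38 with 0 of 30 passing over all genes or over the list alone (camera adjusted p = 2.5e-07; adjusted p = 0.507 with an estimated correlation). Blood cell genes, some of which are uncertain because their counts are split, were shifted the same way (0 of 9 passing, camera adjusted p = 0.0442; adjusted p = 0.507 with an estimated correlation), with scores of 0.51, 0.80 and 0.68 in stressed KO and -0.54, -0.30 and 0.01 in stressed WT; without stressed WT library 1 or stressed KO library 2 the list did not pass (0.157 and 0.0972). Myelin genes had a median of -0.33 with 0 of 25 passing either way (camera adjusted p = 2.5e-07; adjusted p = 0.529 with an estimated correlation), beside myelin scores of 0.17, 0.29 and 0.82 in stressed WT and 0.64, -0.36 and -0.39 in stressed KO. Striatal markers had a median of 0.80, with 0 of 19 passing and 6 higher adjusted over the list alone (camera adjusted p = 1.6e-05; adjusted p = 0.515 with an estimated correlation), and a camera adjusted p of 0.195 without stressed KO library 1. The substrain list had 3 of 12 higher and a median of -0.03. Its mean of 0.22 and its test were upward (camera adjusted p = 0.0211; adjusted p = 0.496 with an estimated correlation); adjusted over the list alone 3 were higher and 2 lower. Without stressed KO library 2 the list did not pass (0.0560). Calcium channel genes did not pass as a list (camera adjusted p = 0.0505), with 0 of 22 passing over all genes or over the list alone; the list leaves out Cacna1g.

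The edgeR test called 38 genes between stressed KO and stressed WT, 13 higher and 25 lower in KO, and the groups of 3358 genes (22.1%, against 10% by chance) did not overlap. Unstressed WT libraries 1 and 2 enter this test only through the gene filter, the scaling and the shared estimate of spread. All of these were redone in the fit without them. The count was 19 and 23 without stressed WT library 2 or 3 and 25, 22 and 25 without stressed KO library 1, 2 or 3; DESeq2 called 290 genes. Of the 13 higher genes 9 were also called higher without stress (1.45 would be shared by independent lists), and of the 25 lower genes 17 were also lower (3.01 by independence).

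Averaged over stress, KO again differed from WT by Wdfy1 (log2 1.72 ± 0.07, SE), Gabra2 (1.23 ± 0.07) and Cacna1g (-1.06 ± 0.06). Lsp1 (1.49), Cabp7, Wfdc18, Cfap46, Nadsyn1, Drd5, a dopamine receptor (1.11 ± 0.20), Sebox, Oprk1, the kappa opioid receptor (1.04 ± 0.26), and Cda were also higher. All of these but Cfap46 and Nadsyn1 were lowest in unstressed WT libraries 1 and 2. In unstressed WT libraries 1 to 3, Lsp1 stood at 1.96, 1.75 and 4.37 CPM. Drd5 stood at 1.82, 2.15 and 2.68 CPM there, and Oprk1 at 2.20, 3.62 and 3.78 CPM. Oprk1 (16.1 CPM) and Drd5 (9.85 CPM) were highest in stressed KO library 1, the one with strong striatal markers. Among the lower genes were Plin4, a lipid droplet protein (-1.37 ± 0.19), Tbx21, Th, Wnk4, Aim1 and Mid1. Mid1, which overlaps another tested gene, stood at 27.3 CPM in stressed KO library 1, above the 19.1, 13.6 and 19.9 CPM of stressed WT. In the other KO libraries it stood at 8.77 CPM or less. Tbx21, Th, Wnk4 and Aim1 were highest in unstressed WT libraries 1 and 2, the libraries with strong olfactory bulb markers: Th stood at 94.2 and 103 CPM there and at 13.6 CPM in library 3, and Tbx21 at 29.4, 24.7 and 2.29 CPM. Glucocorticoid-responsive genes were lower for 7 of 27 and for 12 adjusted over the list alone. Their median was -0.25, with a camera adjusted p of 1.5e-05 (adjusted p = 0.565 with an estimated correlation), with Plin4, Fkbp5 (-0.29 ± 0.06), Klf9 (-0.24 ± 0.05) and Nostrin (-0.63 ± 0.16) leading. Immediate early genes were lower for 4 of 32, and 2 were higher and 8 lower adjusted over the list alone (median -0.16, camera adjusted p = 0.0050; adjusted p = 0.733 with an estimated correlation); Fosb (-0.57 ± 0.11), Egr1 (-0.90 ± 0.18), Egr4 (-0.67 ± 0.16) and Maff (-0.88 ± 0.23) were those that passed, and without stressed KO library 1 the list did not (0.0616). Endoplasmic reticulum stress genes were lower for 6 of 25 and for 7 adjusted over the list alone, with Sesn2 at -0.50 ± 0.07 and Atf4 at -0.38 ± 0.05. Their median was -0.07, with a camera adjusted p of 0.0163 (adjusted p = 0.730 with an estimated correlation), and of 0.0561, 0.0556 and 0.0726 without unstressed WT library 3, stressed WT library 2 or stressed KO library 2. Calcium channel genes were lower for 2 of 22, Cacna1i (-0.49 ± 0.10) and Cacna1c (-0.39 ± 0.09), and for 6 adjusted over the list alone. Their median was -0.15, with a camera adjusted p of 0.0084 (adjusted p = 0.694 with an estimated correlation). Mean scores of that list were 0.24 in unstressed WT, most in libraries 1 and 2, -0.03 in stressed WT, and -0.08 and -0.12 in unstressed and stressed KO. Cholesterol synthesis genes were higher for 10 of 24 and for 15 adjusted over the list alone (median 0.26, camera adjusted p = 8.9e-10; adjusted p = 0.565 with an estimated correlation); between the stressed groups the list did not pass (camera adjusted p = 0.171). Oligodendrocyte precursor markers were lower for 2 of 12, Gpr17 (-0.69 ± 0.07) and Vcan (-0.41 ± 0.11), also over the list alone. Their median was -0.34, with a camera adjusted p of 0.0079 (adjusted p = 0.694 with an estimated correlation). The 31 tested genes near Cacna1g did not pass as a list (camera adjusted p = 0.285), and 2 of them were higher, also over the list alone.

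Averaged over stress, edgeR called 962 genes, 472 higher and 490 lower in KO. It called 78 without unstressed WT libraries 1 and 2. Olfactory bulb markers, with a score of 2.47 and 2.39 in those libraries, were lower in KO for 3 of 14 members with all libraries (12 adjusted over the list alone, camera adjusted p = 1.5e-05; adjusted p = 0.730 with an estimated correlation). Without library 1, 2 or 3 the count was 407, 168 and 3308 for unstressed WT, 164, 600 and 382 for stressed WT, 387, 258 and 578 for unstressed KO, and 590, 383 and 228 for stressed KO; DESeq2 called 1902 genes.

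Whether the stress effect differed between genotypes was tested as an interaction. Pakap (log2 -1.32 ± 0.18, SE, uncertain), Erdr1 (2.09 ± 0.29), Lrrc45 (0.73), Pnisr (0.92), Pcgf2 (1.01), Adamts10 (0.84), Ndfip2 (-0.81), Pan2 (0.91), Cep164 (0.93) and Ano6 (1.20) had the smallest p, and none passed (edgeR adjusted p = 0.0506 for each). Erdr1 stood at 100.4 CPM in unstressed WT and 38.3, 33.7 and 55.0 CPM in stressed WT, unstressed KO and stressed KO. EdgeR called 0 genes, with 4330 at an unadjusted p under 0.05; DESeq2 called 1865. Without unstressed WT library 3 edgeR called 3851 genes, without unstressed KO library 1 it called 46, without stressed KO library 1 it called 1, and without unstressed WT libraries 1 and 2 it called 0. By camera, 16 of 38 lists differed in their stress effect between genotypes, 7 up and 9 down in KO relative to WT, and 0 with an estimated correlation. Across 15199 genes, the correlation of stress effects in WT and KO was -0.102 (Spearman -0.107). The correlation of genotype effects without and with stress was 0.021 (Spearman -0.012). Genes are not independent replicates, so no p is attached. On leaving out 1 library, the first turned to 0.010 without unstressed KO library 3. The second turned to -0.014 without unstressed WT library 3, -0.180 and -0.016 without stressed WT library 1 or 3, and -0.012 and -0.00537 without unstressed KO library 1 or 2.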

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

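The tests of shared reads and of the time of day, the fits with the olfactory bulb score, the thinned counts and the fits without unstressed WT libraries 1 and 2 were chosen only after the results they bear on were seen; the other tests were set out before their results.

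A test of the interaction itself singled out 16 gene lists whose stress effect differed between KO and WT; values are the median log2 difference of the stress effects, KO minus WT. It was negative for potassium, sodium and HCN channels (-0.315), presynaptic vesicle machinery (-0.243), postsynaptic density (-0.274), calcium handling and calcineurin-CaMK signalling (-0.295), oligodendrocyte and myelin genes (-0.558), endoplasmic reticulum stress and integrated stress response (-0.207), cholesterol synthesis (-0.369), oxidative phosphorylation subunits (-0.422) and cytosolic ribosomal proteins (-0.312). It was positive for endothelial (0.355), mural cell (0.562), meningeal (1.93), choroid plexus (1.05), thalamic and septal (0.89) and olfactory bulb markers (2.00), and for interferon-stimulated genes (0.491). With an estimated correlation 0 of the 16 passed, and without unstressed WT libraries 1 and 2 camera called 7 of them.

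The counts of genes called against unstressed WT, 3322 for stress and 3529 for KO, were far above the counts of 38 and 3 that do not involve that group. Library depth is argued against: with every library thinned to the smallest total, 2822 genes were still called for stress in WT. Olfactory bulb tissue in unstressed WT libraries 1 and 2 may contribute, since all 14 markers were highest in those libraries, though 10 are at 1 CPM or more in each of the 10 other libraries and 4 stand in another list; among the 9 libraries of the other groups, 59.14% of the called genes followed the olfactory score opposite to their stress change, with a jackknife SE of 18.2 (added after the value was seen), against 50.54% of uncalled genes. With the score as a covariate the calls ended because the median absolute log2 fold change of the called genes went from 0.483 to 0.318 and the median SE from 0.12 to 0.153, while 98.3% kept their sign. A stress response of WT mice stays open too: the median fold against unstressed WT library 3 was 0.525 of that against libraries 1 and 2 (spread 0.316 over genes), so the dissection and the stress response cannot be told apart in 3 libraries.

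Wdfy1, Gabra2 and Nnt stood out among the 38 genes called between stressed KO and WT, and 15 of the 38 were also called without stress against unstressed WT library 3 alone, a group of 1 library. Reads shared between near-identical gene copies are argued against as the whole cause, since 11 of the 38 genes (28.9%, against 5.25% of tested genes) carry decimal counts in at least 6 libraries, and stay open for those 11. A segment carried over around Cacna1g stays open. Within 10 Mb of it lay 0 other called genes, but only 0.653 of 35 would be expected there by chance, so this count cannot decide. A different colony background of KO and WT mice is a candidate explanation: 6 of 26 calls without shared reads lay within 1 Mb of another such call, against a median of 0 and a 95th percentile of 4 in a permutation test of 10000 random gene sets (p = 0.0104). The 6 lay on chromosomes 4 and 7. Wdfy1, Gabra2 and Nnt, on chromosomes 1, 5 and 13, were not among them, so this test does not bear on those genes singly. An effect of the lost channel on any of these genes stays open, because genotype and colony go together.

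Dbp and Ciart were higher after stress in both genotypes, with Dbp in genes changed by stress averaged over genotypes. Olfactory bulb tissue in unstressed WT libraries 1 and 2 is argued against for Dbp. With the olfactory score as a covariate the stress effect on Dbp was 0.843 (edgeR adjusted p = 0.0403, against 0.0040 without it). Over the alternatives for this result the adjusted p ran from 3.9e-17 with DESeq2 to 0.0403. Of the 6 genes called for stress on average, only Dbp stayed called with that covariate. Ciart lost its call with the covariate. Its rise in KO, which did not pass singly, does not involve those WT libraries. There it stood at 8.05, 8.94 and 10.3 CPM without stress and at 13.4, 17.02 and 18.7 CPM with it. These values argue against olfactory bulb tissue in those WT libraries for the rise of Ciart in KO. For its rise in WT this explanation stays open. The time of day at dissection may differ between stressed and unstressed mice: 11 of 11 genes that peak with Dbp and Per were higher and 5 of 5 that peak with Arntl lower, a mean difference of 0.522 on the log2 scale (0.439 in WT and 0.606 in KO). Because Dbp and Ciart prompted that test, it was repeated without the 8 phase genes singled out before: 5 of 5 and 3 of 3 others went the same way, with a difference of 0.292 (exact permutation of the phase labels, one-sided p = 0.0179, the smallest that 56 assignments can give, across genes that are not independent). Those other genes also belong to the clock list, whose shift in the same libraries had been seen before, so the repeat is not independent of it. A shift of the clock by stress itself would move the same genes and was not tested, so both this shift and the time of day stay open.

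Other splits of the same libraries bear on whether chance can be excluded. For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05; in each, 1 split, the real one, reached its own count. That was 3322 genes for stress in WT (highest other split 0), 3 for stress in KO (0), 3529 for genotype without stress (1) and 38 for genotype with stress (0). For the averages, 2 of 100 splits reached the 6 genes of stress and 1 of 100 the 962 of genotype (highest other 416), the real splits included. These shares do not exclude chance. Splits that part unstressed WT libraries 1 and 2 put the difference of these libraries into the spread, which hinders calls. For stress, a split other than the real one called 781. For the interaction the splits say nothing: its real count is 0, which 100 of 100 splits reach by definition. A split that called 781 genes for stress on average, against 6, and one that called 660 for the interaction, against 0, point to a structure of the samples.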

How the results depend on the processing

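Leaving out any 2 unstressed WT libraries, leaving out 1 and 2 together with stressed KO library 1, estimated correlations without 1 and 2, the marker scores as covariates and the thinned counts were chosen only after the data were seen; the other settings were planned. The cause of a change was not tested except where stated. The KO level of Cacna1g kept its direction and its side of the threshold in every setting, at -0.98 to -1.09 (log2, averaged over stress). The counts for stress in WT and for genotype without stress moved by less than 1.5 times with RLE size factors, no filter, DESeq2, the replicate block, ribosomal protein genes left out and thinned counts; the other counts moved as follows. The smallest library, stressed KO library 3 with 15469590 counts, sets the limit of depth.

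For stress in WT (3322 genes), 1 was called with only the compared groups in the fit, 0 with 1 surrogate variable, 0 without unstressed WT libraries 1 and 2, 3 when stressed KO library 1 was also left out, 0 with the olfactory score and 0 with olfactory and striatal scores. For stress in KO (3), DESeq2 called 44, the surrogate variable 7, leaving out the 3 libraries 9, the olfactory score 6 and both scores 9. For genotype without stress (3529), the compared groups alone gave 18, the surrogate variable 17, leaving out the 2 WT libraries 18, leaving out the 3 libraries 28, the olfactory score 14 and both scores 15. For genotype with stress (38), DESeq2 called 290, the surrogate variable 159, leaving out the 2 WT libraries 82 and the olfactory score 99. For the interaction (0 in edgeR), RLE size factors gave 198, no filter 143, DESeq2 1865, ribosomal protein genes left out 94 and thinned counts 116; its smallest adjusted p of 0.0506 lies just above the threshold. For stress averaged over genotypes (6), DESeq2 called 1198, and the surrogate variable, leaving out the 2 WT libraries and the olfactory score gave 1 each. For genotype averaged over stress (962), DESeq2 called 1902, the surrogate variable 211, leaving out the 2 WT libraries 78, leaving out the 3 libraries 114, the olfactory score 44 and both scores 63. Leaving out 2 unstressed WT libraries leaves 1 in that group. With library 1 or 2 kept in place of 3, genes were still called for stress in WT and for genotype without stress. Those libraries stood far out on the first principal component, at -61.9 and -61.1, against -7.55 for library 3. Whether 1 library can give calls for the smaller differences of library 3 is therefore not shown.

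Leaving out 1 library in turn gave 0 to 5635 genes for stress in WT, 1 to 5 for stress in KO, 234 to 5729 for genotype without stress, 19 to 26 for genotype with stress, 0 to 3851 for the interaction, 2 to 3003 for stress on average and 164 to 3308 for genotype on average, and -1.09 to -1.02 for the Cacna1g level. Camera called 13 to 18 lists for stress in WT (15 with all libraries), 9 to 18 in KO (11), 7 to 15 for genotype without stress (12), 13 to 21 with stress (15), 15 to 18 for the interaction (16), 13 to 20 for stress on average (16) and 12 to 18 for genotype on average (13). With an estimated correlation 0 lists were called in each comparison, with all libraries or without the 2 WT libraries; fry called 3, 0, 2, 2, 0, 0 and 5 in the same order. Without the 2 WT libraries camera called 9 lists for the interaction. The correlation of stress effects in WT and KO was -0.0028 over strongly expressed genes and -0.015 without the 2 WT libraries, and -0.231 to 0.010 on leaving out 1 library. The correlation of genotype effects without and with stress was 0.119 over strongly expressed genes, 0.183 without the 2 WT libraries, 0.102 with the olfactory score, and -0.180 to 0.0998 on leaving out 1 library.

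Among single genes, Cdhr1 turned from lower to higher in unstressed KO with 1 surrogate variable (0.17), the olfactory score (0.32) or both scores (0.25), and Eomes with the olfactory score (0.0965). Both genes are members of the list that makes up the olfactory score, so a fit with that score takes out their difference largely by construction. Cacna1g in genes changed by stress in KO, where it did not pass, stood at -0.064 without unstressed KO library 2 and -0.0596 without stressed KO library 2, within a range of -0.064 to 0.0615 on leaving out 1 library. Of 176 gene results, 166 were on the same side of the threshold with RLE size factors and 10 newly passed; with DESeq2 these were 153 and 22, and 1 lost its call. Without the 2 WT libraries 77 were on the same side and 99 lost their call, with a median absolute log2 fold change of 0.924 against 1.53 with all libraries and a median SE of 0.326 against 0.315.

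The replicate numbers do not pair the libraries: over 18 same-numbered pairs from different groups the correlation of deviations had a median of -0.012 (range -0.246 to 0.364), 4 were above 0.1, and 5 of 12 libraries correlated best with their own number. With the replicate number as a block, edgeR called 25 genes for stress on average against 6, and the 6 other counts stayed within 1.5 times.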

Other observations

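The gene groups and genes in this part were looked at only after their values were seen.

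Pigment-cell genes varied between libraries within both KO groups. Dct, an enzyme of melanin synthesis, stood at 17.6 and 9.17 CPM in unstressed KO libraries 2 and 3 and at 15.3 and 10.8 CPM in stressed KO libraries 2 and 3, and at 3.19 CPM or less in the other 8. Tyrp1, another melanin gene, stood at 2.78, 2.09, 3.47 and 2.75 CPM in the same 4 libraries and at 2.27 and 4.14 CPM in unstressed WT libraries 1 and 2. Immediate early genes varied within stressed KO: Arc stood at 28.1, 41.7 and 74.2 CPM in libraries 1 to 3 and Fos at 4.67, 11.04 and 17.9 CPM, where library 1 is the one with a striatal marker score of 1.71.

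Pakap fell with stress in KO from 30.4 to 11.8 CPM. It overlaps Akap2, which stood at 66.9, 59.3 and 60.3 CPM in unstressed KO and 77.0, 79.9 and 73.9 CPM in stressed KO. The sum of both was 92.6 ± 4.73 CPM in unstressed KO and 88.8 ± 4.17 CPM in stressed KO (SD, n = 3 each), closer than either gene alone.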
